A study of Caenorhabditis elegans with 2 samples.

How the data were processed

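PAG-3 fused to GFP and FLAG was mapped by ChIP-seq with an antibody against GFP in whole L1 larvae of 2 biological replicates, which formed 1 group. Per the labels, chromatin was sheared by sonication and each replicate was a separate biological sample. Groups and replicate numbers were taken from the labels. The strain carried an unc-119 mutation and an integrated transgene, and a possible control experiment named in the labels was not used here.

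For each replicate and for both replicates together, the authors deposited a ranked list of 30000 regions, described per the file headers and descriptions as peaks and background made as input for IDR. Each list was derived from alignments on ce11 against 1 control file, and a second version of each was made on ce10. The deposited peak set thresholded by IDR held 910 peaks on ce11 and 960 on ce10. The aligner, the peak caller and their versions are not given in the sources used here. The deposited signal of a region is its height as the authors' caller gave it, on a scale that is not stated. It was used to rank and describe regions within a list, and its level was not compared between lists. The deposited score in the column for q-values included values below 0 and was not used in any test. The deposited summit offset gave each summit. Most regions had one fixed width per list, 340 bp in the thresholded set (97.9% of its peaks), 330 bp in replicate 1 and 316 bp in replicate 2. Width entered only the alternative definitions of overlap by shared bases, whose replicate overlap was tested against 99 shifts. The 19 narrower peaks of the thresholded set included 17 of the 20 with the highest signal. On both assemblies the thresholded set was identical to the same number of regions with the highest signal in the list called on both replicates together.

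Because a fixed number of regions was listed per replicate, the count of regions says nothing of enrichment, and the tail of each list is background. Calling against a control can reduce peaks that arise from open chromatin, but how far it did so cannot be seen in the lists. Read depth was unknown, so no interval for depth was computed.

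Gene positions came from Ensembl release 115 on WBcel235, the assembly of the ce11 lists, and sequence from the matching RefSeq genome. All ce11 regions lay within the lengths of the 6 nuclear chromosomes of that reference. The ce10 lists were used without annotation. Each of the 19973 protein-coding genes had 1 start, the outer end of its gene model, and a promoter window from 1000 bp upstream to 200 bp downstream. A summit was given to the first of promoter window, coding exon, 5' untranslated region, 3' untranslated region, intron, non-coding gene and intergenic sequence that held it. Genes of piRNAs were not counted as non-coding genes. A promoter window could be shared, and 98 peaks lay in the windows of more than 1 gene. Trans-spliced genes can start upstream of their annotated start.

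Replicates were compared by the share of the 910 highest regions of replicate 1 with a summit within 100 bp of one in replicate 2. Positions were tested against 1000 circular shifts of the summits within each chromosome, which keep their spacing (1-sided permutation test). The smallest p that these shifts can give is 0.000999. Signals of both replicates were correlated over matched peaks, with 1000 bootstrap draws over peaks. The X chromosome was tested with an exact binomial test. Medians of log2 signal were compared with a permutation test of 100000 resamples. The 34 gene lists were written before the data were examined, as were the main tests and the rule for genes named in the text. Each list was compared with all other genes by a two-sided Fisher exact test with Benjamini-Hochberg adjustment over the 34 lists. Genes are not independent replicates, since neighbours can share a peak. Sequences were counted on either strand within 50 bp of the summit and in windows centred 300 bp to each side, and compared by exact McNemar tests, of which the larger p was kept. The floor for a count of 0 was 3 counts. Intervals of shares are Wilson 95% intervals.

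By the rule for named genes, the text names the genes whose promoter windows hold the 20 peaks of highest signal, or else the gene of the nearest protein-coding start. It also names pag-3, unc-119 and 8 genes of touch and ventral cord neurons, and for each list called the 4 members with the highest promoter peak. Other genes were named after their values were seen.

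Alternatives were each replicate alone, the higher-signal part of the peaks (50%), the peaks without the 10% of highest signal, other promoter windows (500 and 2000 bp), other definitions of overlap, the ce10 lists, a background of genes with any pooled region, nearest starts and other forms of the Gfi1 site. In tests on simulated data over 19973 genes, 95.8% of lists given an odds ratio of 10 in 20 draws were recovered, and 1.25% of unchanged lists were called. Only larger lists were given this odds ratio, genes were drawn independently, and no lowered share was simulated. Recovery of small or depleted lists was therefore not measured. Random summit sets reached p under 0.05 for the promoter share in 5% of cases. These sets were few and their summits were placed independently, so this rate is rough and does not cover clustered peaks. A 6-mer planted in 200 windows ranked 1. In that test 3 other 6-mers, which overlap the planted sequence, were also called higher. A shift of 0.5 SD between medians was recovered as 0.421 in a single draw. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.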

Results

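Chromatin immunoprecipitation with sequencing (ChIP-seq) was used to map PAG-3 in whole Caenorhabditis elegans larvae. PAG-3 is a zinc finger protein of the Gfi1 family with known roles in the fate of touch neurons and ventral cord neurons. The transgenic strain OP154 carried PAG-3 fused to GFP and FLAG at its C-terminus, and the protein was precipitated with an antibody against GFP. Starved, synchronized hermaphrodites of the first larval stage (L1) were collected 6 hours after synchronization, and 2 biological replicates formed the 1 group of the series. No control sample was analysed here, so the comparisons were between replicates, between parts of the genome and between groups of genes. No value in the lists showed which protein carried the tag, and regions that recur in the ChIP-seq of many factors were not marked here, so the peaks are those of the precipitate labelled PAG-3. The number of reads behind each region was unknown, because the peak lists give no read counts. Positions are those of the ce11 assembly (WBcel235), counted from 1.

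The peak set thresholded on reproducibility (the irreproducible discovery rate, IDR) held 910 peaks. The highest lay in an intron of peb-1, which encodes a DNA-binding protein of the pharynx, at 2215164 to 2215473 on chromosome X with a signal of 1509. It ranked first in each replicate, with a signal of 1165 in replicate 1 and 339 in replicate 2. The next were in an intron of F46H5.3 (signal 661) and 271 bp upstream of F40A3.6 (signal 619). The peak 789 bp upstream of tln-1, which encodes talin, had a signal of 559.7, and one 1134 bp upstream of C46G7.2 had 548. An intron of mup-4, a gene of epidermal attachment to muscle, carried a peak of 540.3, and an intron of unc-89, which encodes the giant muscle protein obscurin, carried one of 532.

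The other 13 of the highest 20 peaks had signals from 299.1 to 468. The genes with a promoter peak among them were T25F10.1 (468, a summit that also lay within clik-1), unc-112 (377), lgc-34 (376), M03F4.4 (353), B0310.1 (316) and the shared promoter of cdc-14 and ttc-4 (299.6). Introns of unc-54 (391), fbxl-4 (339) and C15A11.2 (305) held others. The remaining summits lay 1078 bp upstream of atn-1 (349.9), which encodes alpha-actinin, 1453 bp upstream of Y69A2AR.1 (325), 1469 bp upstream of twk-18 (303) and 1190 bp upstream of pfkb-1.2 (299.1). Of these 20 summits, 8 were in promoter windows, 7 in introns, 4 in intergenic sequence and 1 in a non-coding gene. The same regions ranked at or above 26 in replicate 1 and at or above 28 in replicate 2. The other 890 peaks had a median signal of 58.1.

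**Figure D1:**
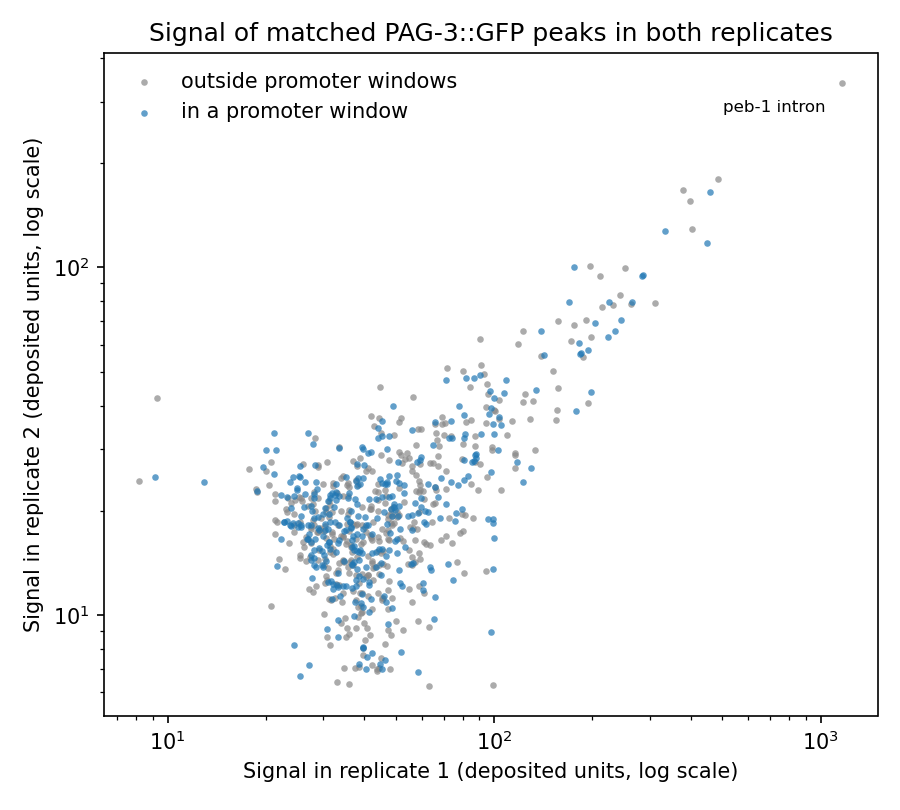
Deposited signal of each of the 751 peaks matched in both replicates, replicate 1 on the x axis and replicate 2 on the y axis (log scales), with blue points for summits in promoter windows. The peb-1 intron stands at 1165 and 339, and the spread of replicate 2 widens among the lower peaks. The peaks were chosen on the signal of both replicates together, which can shape this spread.

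The replicates were compared by the positions of their 910 highest regions. Of those in replicate 1, 349 had a summit within 100 bp of one in replicate 2 (38.4%, Wilson 95% interval 35.2 to 41.6). Circular shifts of the replicate 2 regions gave a mean of 0.191% and a highest value of 0.769% (1-sided permutation p = 0.000999, the smallest that 1000 shifts can give). Of the 910 thresholded peaks, 78.02% (75.2 to 80.6) matched a top region of replicate 1 and 52.6% (49.4 to 55.9) one of replicate 2. In the full lists of 30000 regions, 883 peaks had a match in replicate 1 and 773 in replicate 2. The peaks matched in both numbered 751, and their signals had a Spearman rho of 0.41 (bootstrap 95% interval 0.35 to 0.48) and a Pearson r of 0.63 on the log2 scale. This correlation is across peaks, which are not independent replicates. The thresholded set was identical to the 910 regions of highest signal in the list called on both replicates together. Such a cut on the joint signal can change the correlation among the peaks kept. The rho therefore describes these peaks and does not measure replicate agreement over all regions.

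Summits were concentrated near gene starts. Of the 910 summits, 408 lay in the window from 1000 bp upstream to 200 bp downstream of a protein-coding start (44.8%, 41.6 to 48.1), 2.14 times the mean of 20.9% in circular shifts (highest shift 25.5%, 1-sided permutation p = 0.000999). Coding exons held 10 summits (1.099%, 0.598 to 2.01) against 19.9% in shifts, and introns 209 (22.97%, 20.4 to 25.8) against 30.9%, both lower than in every shift. Promoter windows were counted first, so their excess lowers the share left for every other place. The intron share can therefore not be read as avoidance of introns, and shares among summits outside the windows were not compared. Intergenic sequence outside the windows held 239 summits (26.3%, 23.5 to 29.2) against 22.1%. 5' untranslated regions outside promoter windows held 12 (1.32%, 0.756 to 2.29) against 0.560%, and 3' untranslated regions held 5 (0.549%, 0.235 to 1.28) against 2.44%. Among all 30000 pooled regions, which include background, 27.3% of summits lay in promoter windows. These intervals, and all others of shares here, are Wilson 95% intervals and cover counting error only.

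Peak height did not differ detectably between promoter windows and the rest of the genome. The median signal was 57.3 for the 408 peaks in promoter windows and 58.6 for the other 502, a log2 difference of -0.032 (two-sided permutation test over peaks, p = 0.311). The interquartile ranges were 29.4 and 30.8. The sign of this small difference turned in either replicate taken alone and with a window of 2000 bp.

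The X chromosome carried more peaks than its length predicts. It held 221 of the 910 peaks (24.3%, 21.6 to 27.2), or 12.5 per Mb, while it makes up 17.7% of the nuclear genome (two-sided exact binomial p = 5.31e-07) and 13.7% of the protein-coding genes (p = 1.23e-17). Chromosome I held 10.7 peaks per Mb and chromosome III 9.79, while II, IV and V held 7.20, 7.09 and 7.55. Of all 30000 pooled regions, 17.97% were on X. Neighbouring peaks are not independent, so these p-values are too small.

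Genes of muscle stood out among the 34 gene lists. A summit lay in the promoter window of 511 of 19973 protein-coding genes (2.56%), and in that of 17 of 46 genes of body wall and pharyngeal muscle (37.0%, 24.5 to 51.4), an odds ratio of 23.1 against all other genes (two-sided Fisher exact test, Benjamini-Hochberg adjusted p over the 34 lists = 1.99e-14). The highest of these promoter peaks were at unc-112 (kindlin, a protein of muscle attachments; signal 377), unc-54 (the main body wall myosin heavy chain; 298), unc-15 (paramyosin; 277) and tnt-2 (troponin T; 239). The others were at mlc-2, unc-97, unc-27, lev-11, zyx-1, mup-2, pat-10, unc-95, pat-3, mlc-3, unc-98, act-1 and unc-89, with signals from 50.7 at unc-89 to 207.9 at mlc-2. The 910 highest regions of replicate 1 alone marked 18 of the 46 genes, and those of replicate 2 alone marked 13. Without the 91 peaks of highest signal, the odds ratio was 11.8 (Fisher exact adjusted p = 1.00e-06).

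The unc-54 locus held several of these peaks. Its promoter summit lay just upstream of the gene start, at 14863601 on chromosome I, with a signal of 225 in replicate 1 and 79.7 in replicate 2. A higher peak of 391 had its summit at 14862291, in an intron, and further summits lay upstream of the gene at 14865038 (signal 78.4) and 14865670 (104.2). At unc-112 the summit was at 14697157 on chromosome V, 503 bp upstream of the start, and ranked 10 in replicate 1 and 12 in replicate 2. The unc-15 summit lay 172 bp upstream of its start, at 7383369 on chromosome I, and that of tnt-2 lay 406 bp upstream, at 8723956 on X.

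**Figure D2:**
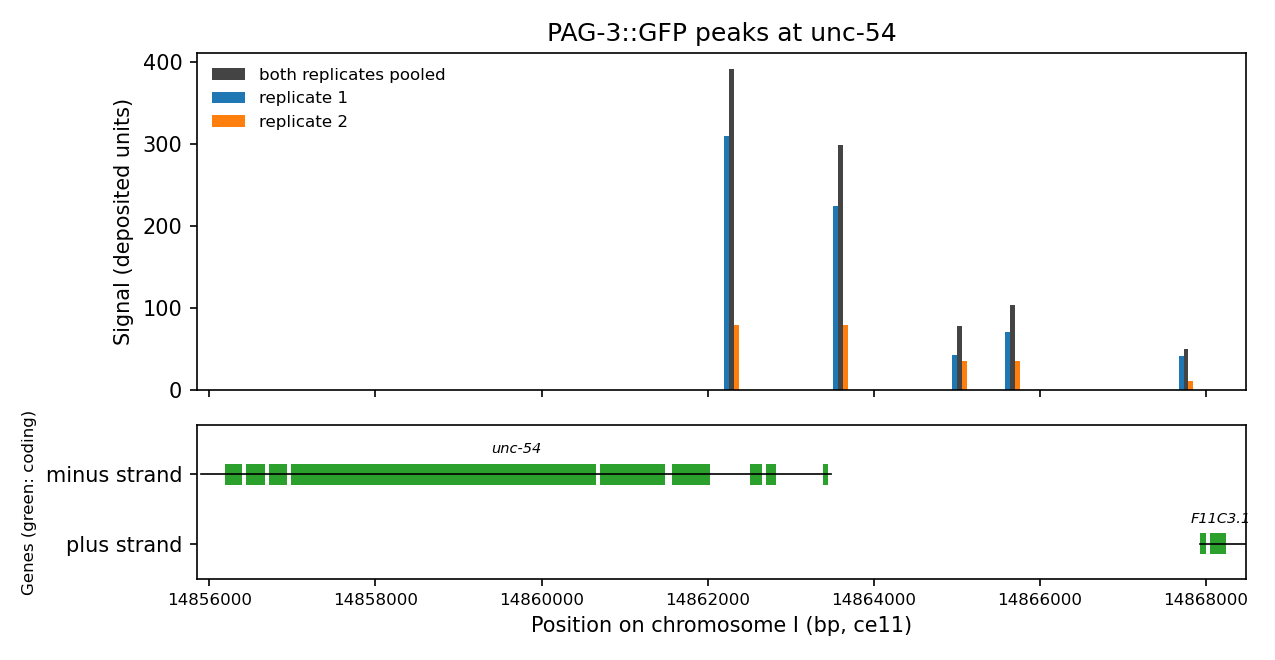
Signal (y axis, deposited units) of the peaks at unc-54 against position on chromosome I (x axis, bp, ce11), with gray bars for the list called on both replicates, blue for replicate 1 and orange for replicate 2, each drawn beside the summit. Coding segments are green, and the 2 highest gray bars stand in an intron (391) and just upstream of the gene start (298). The scale of the signal is not stated, so bar heights are not to be compared between colours.

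Ribosomal protein genes were the other list with a higher share. Promoter peaks lay at 15 of 79 genes of cytosolic ribosomal proteins (18.99%, 11.9 to 29.0; odds ratio 9.17, Fisher exact adjusted p = 1.46e-08). The highest were at rpl-11.2 (signal 277), rpl-15 (119.7), rps-20 (118.6) and rps-12 (113), each with its summit from 172 to 392 bp upstream of the gene start. At rps-20 and rps-12 the summit lay nearer to the start of another protein-coding gene. The rpl-11.2 summit was at 2243010 on X and ranked 35 in replicate 1 and 10 in replicate 2. Against the 8101 genes with any pooled region in the window, the odds ratio fell to 4.96 (Fisher exact adjusted p = 4.34e-05). With each peak given to the nearest gene start, 9 of the 79 genes had one and the odds ratio was 3.02 (Fisher exact adjusted p = 0.0343).

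Chemoreceptor genes, which encode receptors of sensory neurons, were nearly free of promoter peaks. A single gene of 1277, srh-2, had one (0.0783%, odds ratio 0.0279, Fisher exact adjusted p = 2.07e-12), with a signal of 54.7 and a summit 170 bp upstream of its start at 728131 on chromosome V. That summit lay nearer to the start of another protein-coding gene. The top regions of replicate 1 alone and of replicate 2 alone each marked 2 of the 1277 genes (odds ratios 0.0582 and 0.0566). Genes of C-type lectins had none among 237, which allows a share of up to 1.27% (Fisher exact adjusted p = 0.0455). The call for lectins was lost in 7 of 10 alternative settings, among them replicate 2 taken alone (Fisher exact adjusted p = 0.590). Members of both families lie in clusters along chromosomes, so their genes are not independent.

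Genes of neuron identity and function had few promoter peaks. No promoter window of the touch receptor neuron genes (15 genes), neuron identity transcription factors (46), synaptic and pan-neuronal genes (31), flp (31), nlp (71) or ins (38) peptides, dense core vesicle genes (17), GABA genes (11), monoamine genes (22) or glutamate genes (27) held a summit. A count of 0 allows a share from 4.23% for the nlp list up to 27.3% for the GABA list, so none of these passed the test on its own. One gene each had a promoter peak among acetylcholine genes (ric-3), ion channels (shk-1), innexins (inx-13), axon guidance genes (zig-12) and cilia genes (ift-43). In the union of these 15 lists, a test chosen after the values were seen, 5 of 548 genes had a promoter peak (0.912%) against 2.60% of all others (odds ratio 0.344, two-sided Fisher exact p = 0.00865). With a window of 2000 bp, 7 of the 548 genes had one (odds ratio 0.342, Fisher exact p = 0.00149). When each peak was given to the nearest gene start, 22 of the 548 genes had one (4.01% against 4.11%, Fisher exact p = 1). The difference thus depended on how peaks were given to genes.

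Genes known from work on touch neurons and ventral cord neurons were free of thresholded peaks within 5 kb. They were pag-3 itself, mec-3, mec-4, mec-7, unc-86, unc-3, unc-4, egl-44 and egl-46, and the same held for unc-119, the marker gene of the transgene. The promoter windows of unc-4, egl-44 and egl-46 held low pooled regions, with signals of 17.4, 19.9 and 15.9 and ranks of 14244, 9089 and 18707 among 30000. No pooled summit lay in the promoter windows of the other 7 genes. Of all 19973 protein-coding genes, 8101 had a pooled region in the window and 511 a thresholded summit (2.56%). Absences at so few genes can therefore not be called unusual. The share of all genes with a thresholded peak within 5 kb was not computed.

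The remaining lists did not pass the test. Promoter peaks lay at 3 of 28 cell cycle genes (cdc-14, cdc-6 and wee-1.3; Fisher exact adjusted p = 0.231), 2 of 17 heterochronic genes (lin-28 and lin-14; adjusted p = 0.355) and 10 of 212 collagen and cuticle genes (4.72%, 2.58 to 8.46; adjusted p = 0.355). Heterochronic genes, which time larval development, passed when peaks were given to the nearest start, with 5 of 17 genes (Fisher exact adjusted p = 0.00538). They did not pass with the 2000 bp window, with 3 of 17 (Fisher exact adjusted p = 0.121). Unlike a fixed window, nearest starts do not remove the effect of gene length. Of 269 nuclear hormone receptors, 7 had a promoter peak. Counts were 1 of 25 for basic helix-loop-helix genes, 0 of 63 for ceh homeobox genes, 1 of 17 for epidermis regulators, 2 of 94 for intestine genes and 2 of 45 for germline genes. They were 1 of 18 for programmed cell death, 1 of 31 for Wnt and Notch signalling, 3 of 75 for heat shock and stress, 1 of 50 for histones, 0 of 31 for major sperm proteins and 0 of 74 for cytochrome P450 genes.

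**Figure D3:**
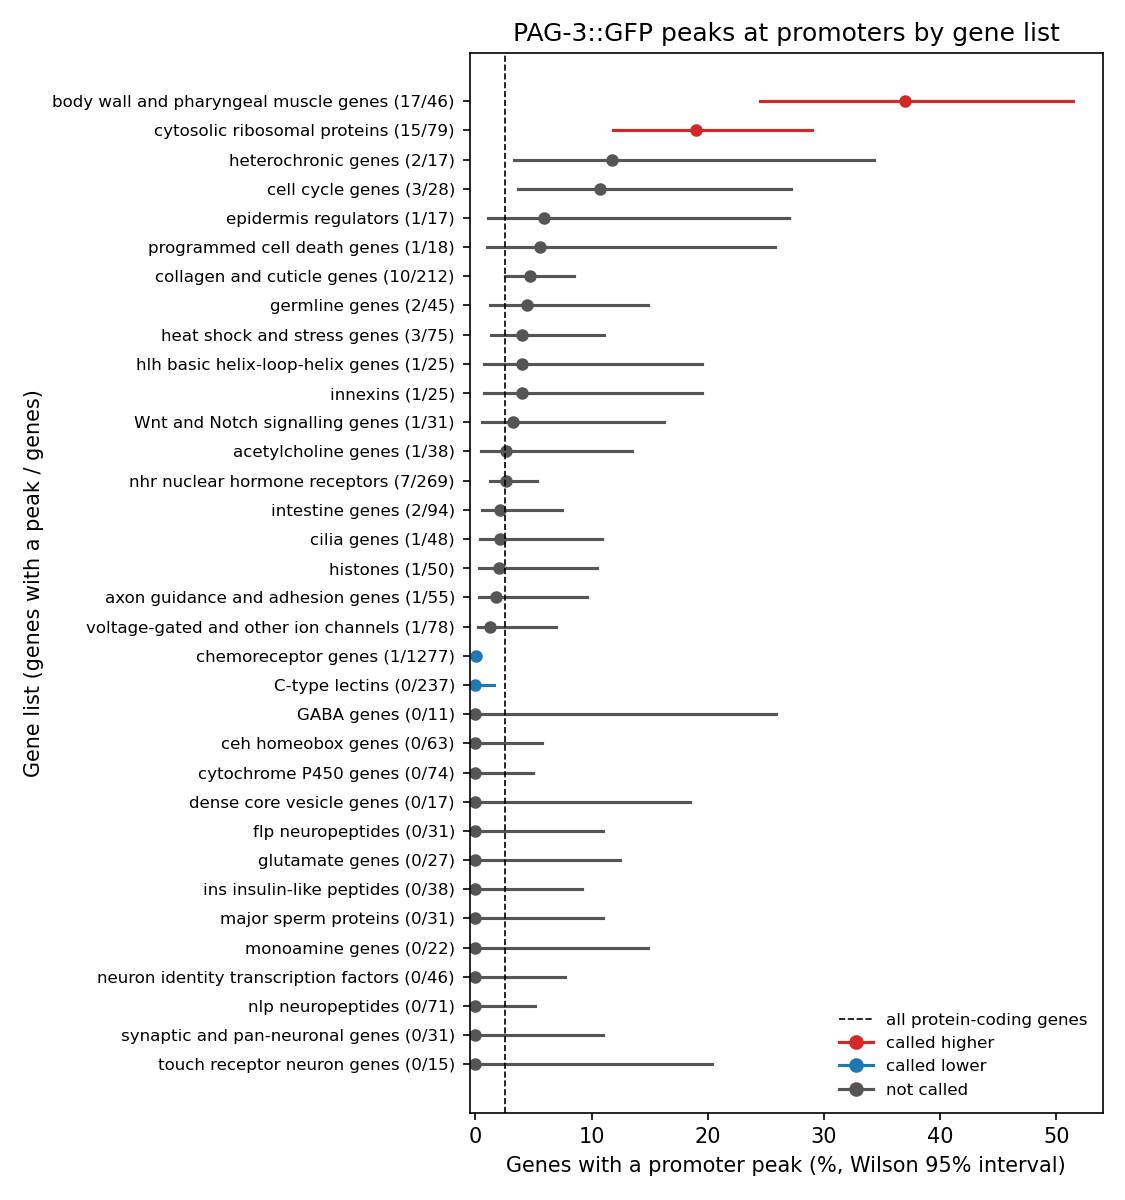
Share of the genes of each list with a summit in the promoter window (x axis, percent, with Wilson 95% intervals), one list per line, with red for lists called higher, blue for lists called lower and a dashed line for all protein-coding genes (2.56%). Muscle genes (37.0%) and ribosomal protein genes (18.99%) stand to the right of the other lists.

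The core of the site bound by vertebrate Gfi1, AATCAC, was no more frequent at summits than beside them. It occurred within 50 bp of 46 of 910 summits (5.05%, 3.81 to 6.68) and in 5.11% of windows 300 bp away, a ratio of 0.99 (exact McNemar test, two-sided, the larger p of both flanks = 0.744). By this ratio it ranked 1173 among 2080 distinct 6-mers, and 16 among the 60 of its base composition, whose median ratio was 0.73. None of the highest 20 peaks held it. The shorter AATCA and the related AAATCA were less frequent at summits than in the flanks, at 23.7% against 30.1% (exact McNemar p = 0.0327) and 10% against 15.5% (p = 0.00086). The ratios of AATCA and AAATCA, 0.79 and 0.65, were above the medians of words of the same composition, 0.64 for AATCA (rank 1 of 20) and 0.52 for AAATCA (rank 4 of 30), a comparison added after the values were seen and given without a test.

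Other sequences were more frequent at summits. In a scan of all 2080 6-mers, 267 were higher and 213 lower at summits at an adjusted p under 0.05, while the GC content was 43.8% at summits and 34.6% in the flanks. GAGAGA lay within 50 bp of 28.8% of summits (25.9 to 31.8) against 7.20% of flanks (adjusted exact McNemar p = 2.07e-28). ATGGCA was found at 15.2% (13.0 to 17.6) against 3.19% (adjusted exact McNemar p = 2.66e-16), and GACGCA at 11.98% (10.03 to 14.2) against 2.31% (adjusted p = 6.91e-13). CACGTG was found at 5.71% against 1.54% (adjusted exact McNemar p = 0.000157). ATGGCA and GACGCA had the highest ratios among the 180 and 90 6-mers of their base compositions, and GAGAGA ranked 2 among 20. Among the 20 highest peaks, 9 held ATGGCA, 6 GAGAGA and 4 GACGCA. These 6-mers were chosen after their values were seen.

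**Figure D4:**
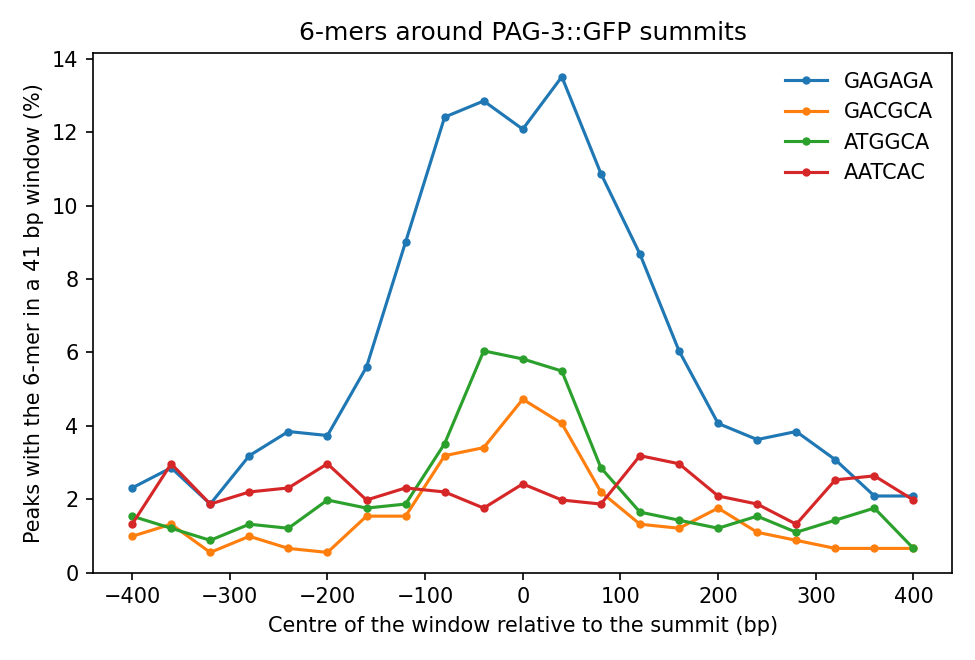
Share of the 910 peaks with each 6-mer in a window of 41 bp (y axis, percent) against the distance of the window from the summit (x axis, bp). GAGAGA stays between 10.9% and 13.5% from -80 to 80 bp, without a maximum at the summit itself (12.1%). It falls to 2.09% at 400 bp, while AATCAC stays between 1.32% and 3.19%.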

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

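The circular shifts for gene lists, the clusters of neighbouring genes, the union of neuronal lists and the 6-mers in subsets of summits were chosen after the data were seen. Replicate overlap, promoter share and X chromosome share kept their direction and stayed past their thresholds under every alternative listed for them; the overlap ranged from 31.7% with 1820 regions to 47.5% with 455. The Spearman rho of 0.41 moved to 0.34 with reciprocal overlap of 50% and to 0.51 over the 400 matched peaks of the higher-signal part. The promoter signal difference turned from -0.032 to between 0.017 and 0.034 (log2) in the lists of single replicates and to 0.020 with the 2000 bp window, and its p stayed above 0.05 throughout. The AATCAC share was 5.71% and 6.59% in single replicates and 5.49% in the higher part of the peaks, where the ratio to the flanks rose above 1 without passing the test. AAATCA (10%) and AATCA (23.7%) were below their flanks and passed it, though above the medians of words of their base composition. The cause of these changes was not tested. Between 3 and 5 gene lists were called in every setting; muscle, ribosomal protein and chemoreceptor genes were called in all of them, with odds ratios of muscle from 11.8 to 37.1, of ribosomal proteins from 3.02 to 11.2 and of chemoreceptors from 0 to 0.0582. Collagen and cuticle genes were called in the higher part of the peaks and against circular shifts. In regions of replicate 2 only, ATGGCA (4.63% against 3.92%, exact McNemar p = 0.771) and GACGCA (5.35% against 2.85%, p = 0.066) lost their calls; they were named from the thresholded set, which leans on replicate 1. The union of neuronal lists lost its call with nearest starts (odds ratio 0.975). Read depth was unknown, so its effect on the peaks of either replicate could not be measured.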

Other observations

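Of the tests of explanations below, those of the transgene loci and of open promoters were set before the data were examined, and the others were chosen after the results were seen.

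At least 3 peaks were nearest to the start of each of 16 genes. Nearest starts do not remove the effect of gene length, and these genes ranged from 39 bp (ZK617.26) to 55184 bp (unc-89). The gene hlh-30, which encodes a transcription factor of autophagy and lipid genes, had 5, with a highest signal of 63.8. The genes unc-54, W02C12.2 and sca-1 (the calcium pump of the sarcoplasmic reticulum) had 4 each, with highest signals of 391, 135 and 134. The 12 genes with 3 peaks were F46H5.3 (highest signal 661), unc-89, mlc-3, ZK617.26, W06H8.6, act-1, lev-11, kin-1, daf-5, ccch-1, ppfr-1 and dyc-1, of which unc-89, mlc-3, act-1 and lev-11 are in the muscle list. By nearest start, 24 of the 46 muscle genes had a peak. Those without a promoter peak included atn-1 (349.9), pat-2 (197, 2984 bp upstream), unc-68 (194, 1433 bp upstream), unc-87 (117) and myo-3 (87.5). Among heterochronic genes, lin-14 had a peak of 213 at 1953 bp downstream of its start, and lin-41, daf-12 and nhr-85 had peaks of 54.7, 56.2 and 48.6. These genes were named after their values were seen.

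A longer sequence joined GACGCA to GAGA. The 8-mer GAGACGCA lay within 50 bp of 62 of 910 summits (6.81%, Wilson 95% interval 5.35 to 8.64) against 0.659% of flanks (exact McNemar p = 8.18e-13). It was present in 62 of the 109 peaks with GACGCA (56.9%). The 10-mer GAGACGCAGA was found at 4.73% against 0.220%.

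Peaks lay at muscle and ribosomal protein genes, and few lay in the promoter windows of neuron genes. Open promoters cannot be told apart: 2 of the 2 lists called higher were still called against genes with any pooled region, but pooled summits lay in promoter windows at 27.3% against 20.9% in shifts, so the bound set beforehand took too weak a measure of openness. Strong transcription stays open for the ribosomal protein genes: 8.70% (4.05 to 17.7) of 69 proteasome, ATP synthase and translation factor genes had a promoter peak, above the 2.54% of other genes (two-sided Fisher exact p = 0.00838) and not detectably below the ribosomal share (p = 0.0984), and no expression values were used to weigh the muscle genes. A protein other than PAG-3, as after an exchange of strain or library, cannot be told apart: the AATCAC ratio of 0.989 and the count of regions at pag-3 (4.25% of genes on X had no more) neither show PAG-3 nor identify another protein. Regions bound in the ChIP-seq of many factors, PAG-3 itself at muscle genes and dilution of signal from few neurons in whole larvae were not tested.

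Regions in the top list of replicate 2 only (561) differed from those of replicate 1 only (561) in sequence: of 20 6-mers picked on the 349 regions in both top lists, at least 1 lay at 39.9% of the former (flanks 30.7%) and 71.7% of the latter (flanks 28.8%; odds ratio 0.263, two-sided Fisher exact p = 6.78e-27), as weaker enrichment in replicate 2 may give, though other differences between the replicates stay open. GAGAGA lay at 13.2% and 33.2%, ATGGCA at 4.63% and 11.9%, and GACGCA at 5.35% and 10.3%, but these were named from the thresholded set, which holds more of the top regions of replicate 1, so their direction was favoured beforehand. Randomly placed background is argued against as the whole source of the regions of replicate 2 only. Of their summits, 43.1% lay in promoter windows, 2.05 times the mean of circular shifts (1-sided permutation p = 0.000999, the smallest possible). Background that itself favours promoter windows stays open, since 27.3% of all pooled summits lay there. Regions of replicate 2 only marked 9 of 79 ribosomal protein genes (Fisher exact adjusted p = 5.50e-05) and 0 of 46 muscle genes. Those of replicate 1 only marked 8 and 5 (Fisher exact adjusted p = 0.000295 and 0.00559), and regions in both top lists marked 7 and 13. The differences between these counts were not tested. No biological explanation was tested, as the replicates share 1 group.

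GAGAGA, GACGCA and ATGGCA at summits were set against base composition and repeats masked in the reference. All 3 were among the 20 6-mers of lowest p on chromosomes I, II and III, a choice made after the 20 of highest ratio there, which held GACGCA alone of them, had been measured. Their ratios on IV, V and X were divided by the median of 6-mers of the same composition. This gave 2.33 (bootstrap 95% interval 1.72 to 3.08), 2.84 (1.92 to 4.58) and 5 (3.38 to 7.25). The 3 were named from all thresholded peaks, which include those on IV, V and X, so that choice may have raised these values. The values therefore cannot decide whether GC content is the whole source of the 3. For the 20 of highest ratio as a set, GC content cannot be told apart either. Their median was 1.41 (lower quartile 0.909), with 7 above 2 times and 6 below the median of their composition. For the 20 of lowest p the median was 2.06 (lower quartile 1.76). Masked repeats are argued against as the whole source, since all 3 of the 6-mers were above 2 times their flanks at the 325 summits with no masked base. Repeats that the reference leaves unmasked were not tested, and no biological explanation was tested.

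No excess of listed regions was seen at the loci of the transgene, but this cannot tell whether extra copies were present. The lists hold a fixed number of regions, and extra copies could cancel against the control file if it shared them. Near pag-3 (20 kb), 5 pooled regions were listed against a median of 13 around genes on X, and 4.25% of genes on X had no more. Near unc-119 (5 kb), 5 were listed against a median of 4, and 70.9% of genes on chromosome III had no more.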
